A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

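RNA of budding yeast was hybridised to 18 two-colour arrays. Each array compared 1 culture with a pool of RNA from 3 W303-1A cultures grown without ethanol. The 6 groups of 3 arrays were the parent W303-1A and the mutants SM1 and CM1, each with 0 or 6.5 % v/v ethanol. Replicates were separate cultures. Replicate 1 of each group was dye-swapped, which gave 6 swapped and 12 normal arrays. Cultures were started from unstressed late exponential cells, RNA was extracted with glass beads and treated with DNase, and cDNA was labelled indirectly with 2 fluorescent dyes. The sampling time was not given in the sources used here.

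Per the labels, the deposited values are normalized log ratios, and they are read here as log2 values. The authors' choice of log base and of centring is not stated, nor is the direction of the ratio. Another base would multiply every printed value by 1 factor without changing a test. The medians of the columns show values centred near 0. They were 3.79e-05, 0.015 and 0.0095 for W303-1A without ethanol, 0.030, 0.010 and 0.014 with ethanol, -0.0041, 0.0099 and 0.025 for SM1 without ethanol, -0.00014, 0 and 0.0018 with ethanol, 0.0043, 0.0091 and 0.0079 for CM1 without ethanol, and 0.0081, 0.024 and 0.0008 with ethanol. How the centring was made stays unknown.

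The rule set for the direction, written before the data were examined, compared the swapped array of each ethanol group with the normal arrays and gave a mixed answer. The correlation across genes was 0.0037 and 0.029 in W303-1A, -0.15 and -0.11 in SM1, and 0.30 and 0.14 in CM1. A test chosen after this result was seen subtracted the arrays without ethanol of the same orientation, and gave -0.42, -0.30 and -0.09, or -0.388, -0.322 and -0.145 with the trend along the probe number removed. With HSP12, which changed sign on the swapped array of all 3 strains, these values were taken to mean red over green in all columns, so swapped arrays were multiplied by -1. This reading is likely rather than certain, least so for CM1, and the opposite reading was run as an alternative.

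The table held 6368 probes with 0 missing values. Of these, 5673 carried 1 gene symbol, 0 carried several and 695 carried none and were left out of the gene counts. The 23 genes with 2 probes were averaged, which left 5650 genes. Signal intensities and backgrounds were not used here, so the precision of a value comes from the spread between arrays. Genome positions are not given, since the build behind the probe annotation is not named.

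A linear model was fitted in limma 3.58.1 under R 4.3.3 to all 18 arrays, with a mean for each group and a term for dye orientation, followed by empirical Bayes moderation. Genes with a Benjamini-Hochberg adjusted p under 0.05 over 5650 genes count as passed. The 12 comparisons were ethanol against none in each strain, each pair of strains at each ethanol level, and the differences between strains in the ethanol response. The model was tested on simulated data with 3 arrays per group. In the 9 pair comparisons 28.4 to 32.05 % of genes changed 2-fold and 81.3 to 83.35 % of those changed 4-fold were recovered. In the 3 response differences 6.95 to 7.9 % and 52.7 to 55.3 % were. Unchanged genes made up 4.97 % of all calls, and 4.60 to 4.94 % of those of the response differences. Whether the rates hold for the real arrays (residual SD 0.24 to 0.61, trend along the probe number) was not tested.

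Gene lists, 31 in all, were written before the data were examined and tested in limma with the competitive cameraPR test at a preset inter-gene correlation of 0.01. Each was tested again with a correlation estimated from the residuals, and with fry, which asks whether a list moves one way on balance and not whether it moves more than other genes. A list adjusted p in the text rests on the preset correlation unless an estimated one is named. An estimated correlation could be higher, such as 0.12 for cytosolic ribosomal proteins. The p was then far larger, also for lists that kept their call. For ethanol in W303-1A it was 0.00277 for chaperones. Counts of list members use the adjustment over all genes, with the count adjusted over the list alone beside it. For the lists called, the median, the mean and the test had the same sign. Chromosomes were tested in the same way.

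Genes named in the text were chosen by a rule written before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes that passed and whose replicates did not overlap, the 4 members of each list with the smallest p, and HSP12, HSP26, HSP104, CTT1, TPS1, GPD1, ADH1, ADH2, PMA1 and OLE1. For response differences the adjusted p alone was used. The text names part of the genes this rule gives. Genes without overlap made up between 12.7 and 26.4 % of genes in the 9 pair comparisons, where chance gives 10 %.

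Alternatives planned were centring each array, quantile normalization, no dye term, a replicate block in place of the dye term, only the groups compared in the fit, array weights, each probe on its own, the normal dye orientation only, the opposite sign on the swapped arrays, and leaving out each array in turn. A filter on missing values removed 0 genes and is void. 4 more were chosen after the data were seen, namely removal of a lowess trend along the probe number with a span of 0.1, removal of a quadratic trend for the chromosomes, all but 2 doubted arrays, and all probes including the unnamed. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.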

Results

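Budding yeast transcripts were measured on 18 two-colour arrays. The parent W303-1A and the ethanol-tolerant mutants SM1 and CM1 were each grown with 0 or 6.5 % v/v ethanol. Each of the 6 groups held 3 separate cultures, 1 array each, set against an RNA pool of the 3 W303-1A cultures without ethanol. The probes with a gene symbol gave 5650 genes. The number of arrays limits precision. Values are log2 differences between groups ± the standard error of the limma fit (n = 3 arrays per group). That error, pooled per gene over all 18 arrays, does not show the spread of a group. The ratio direction was not stated with the values. Sample over pool, once the dye-swapped arrays were turned, is the likely reading, because HSP12, a heat shock gene, stood at 8.12 and 7.92 on the normal arrays of W303-1A with ethanol and at -7.01 on the swapped array. Probes of near-identical genes can read each other's transcripts, so single values within the TDH, ENO, ADH, PHO5, HXT, histone, ribosomal protein and Ty families are uncertain as to the copy.

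The first question was how the parent responded to ethanol. In W303-1A the small heat shock genes HSP12 (7.77 ± 0.54) and HSP26 (5.71 ± 0.46) rose most. CHA1, the serine and threonine deaminase, rose by 4.27 ± 0.35 and TDH1, an isoform of glyceraldehyde-3-phosphate dehydrogenase, by 4.13 ± 0.27. The largest falls among the named genes included DBP2, an RNA helicase gene (-4.39 ± 0.34), FET3, the multicopper oxidase of iron uptake (-4.07 ± 0.52), OLE1, the fatty acid desaturase (-3.47 ± 0.48), and GUA1, the GMP synthase (-3.15 ± 0.32). Of 136 cytosolic ribosomal protein genes 95 fell and 0 rose, with a median of -0.97 and examples RPL6B (-2.46 ± 0.24) and RPS11A (-1.84 ± 0.20). Adjusted over the list alone, 102 fell (list adjusted p = 2.65e-29, or 0.00022 with an estimated correlation). Ribosome biogenesis fell with them, at 45 of 66 genes (50 adjusted over the list alone), with HAS1 at -2.82 ± 0.30 and RPA190, the large subunit of RNA polymerase I, at -2.41 ± 0.29 (list adjusted p = 1.85e-19).

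Sterol synthesis also went down in the parent with ethanol. Of 24 ergosterol genes 20 fell and 0 rose (21 adjusted over the list alone), including HMG1, an HMG-CoA reductase (-2.96 ± 0.31), ERG3 (-2.63 ± 0.27) and ERG11 (-2.25 ± 0.25), and the list median was -1.43 (adjusted p = 1.65e-16). Among 27 heat shock and chaperone genes 14 rose and 0 fell (19 adjusted over the list alone), with HSP31 at 3.61 ± 0.23, the mitochondrial disaggregase HSP78 at 2.24 ± 0.28 and HSP104 at 0.92 ± 0.29 (list adjusted p = 4.84e-12). Of 30 Msn2/4 general stress genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), among them HOR7 (3.41 ± 0.23), DDR2 (1.90 ± 0.23) and STF2 (1.68 ± 0.19), with list adjusted p = 2.27e-11. The catalase gene CTT1 did not pass (-0.68 ± 0.39, adjusted p = 0.23).

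Carbon metabolism moved in W303-1A as well. Of 15 glycolysis genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with ENO1 at 2.86 ± 0.27 and PGK1 at 2.60 ± 0.25 (list adjusted p = 3.97e-09). ALD4, the mitochondrial aldehyde dehydrogenase, rose by 3.20 ± 0.28, and the alcohol dehydrogenase genes ADH1 (1.66 ± 0.32) and ADH2 (1.68 ± 0.32) rose too, while their list of 18 had 6 up and 4 down (6 and 5 adjusted over the list alone) and was not called (adjusted p = 0.219). Trehalose and glycogen metabolism had 8 genes up and 1 down of 21 (9 and 1 adjusted over the list alone), TPS1 at 1.54 ± 0.31 and NTH2 at 1.80 ± 0.37 among them, but that call was lost (adjusted p = 0.0993 with an estimated correlation). Oxidative stress defence had 11 up and 3 down of 28 (12 and 4 adjusted over the list alone; list adjusted p = 0.0032), with the peroxiredoxin gene AHP1 at 3.49 ± 0.25 and the thioredoxin gene TRX2 at 1.58 ± 0.25. Of 7 a-cell specific genes 5 fell (5 adjusted over the list alone; list adjusted p = 4.8e-05), including STE2, the alpha factor receptor (-3.33 ± 0.35), BAR1, the protease that degrades alpha factor (-3.19 ± 0.48), and the pheromone gene MFA1 (-2.54 ± 0.43). SNZ1, of vitamin B6 synthesis, rose by 3.88 ± 0.69, and the weak acid transporter gene PDR12 fell (-2.99 ± 0.37). The glycerol gene GPD1 (0.03 ± 0.25) and the plasma membrane proton pump gene PMA1 (-1.14 ± 0.46) did not pass (adjusted p = 0.951 and 0.0860).

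In all, 1349 of 5650 genes passed in W303-1A, 578 higher and 771 lower with ethanol. 4 further lists were called that an estimated correlation did not keep. Histones and S-phase genes were lower at 8 of 26 genes (adjusted p = 0.0703 with an estimated correlation). The proteasome was higher at 9 of 32 genes (adjusted p = 0.301 with an estimated correlation), glycerol metabolism at 4 of 12 (adjusted p = 0.160 with an estimated correlation) and the mitochondrially encoded genes at 2 of 8, OLI1 (1.58 ± 0.47) and VAR1 (1.60 ± 0.51) (adjusted p = 0.507 with an estimated correlation). Adjusted over the list alone these were 9 lower with 1 higher, 9 higher, 5 higher with 1 lower, and 3 higher. Without the dye term 791 genes passed, with quantile normalization 863 and with array weights 1795.

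The same contrast in the mutant SM1 gave a stress response without the fall of the ribosomal genes. HSP12 rose by 5.0 ± 0.54, HSP31 by 3.01 ± 0.23 and HSP26 by 2.86 ± 0.46. Larger rises than that of HSP12 were those of ANS1 (6.75 ± 0.77) and SIP18, a phospholipid-binding protein of osmotic stress (5.48 ± 0.52). NCA3 (4.89 ± 0.79) and the glycerophosphoinositol permease gene GIT1 (4.67 ± 0.48) rose slightly less than HSP12. Of 30 Msn2/4 genes 10 rose and 0 fell (14 adjusted over the list alone; list adjusted p = 2.19e-15), with DDR2 at 3.72 ± 0.23, YGP1 at 2.11 ± 0.22 and GRE3 at 1.82 ± 0.24. CTT1 rose by 1.73 ± 0.39. Of 27 heat shock and chaperone genes 9 rose and 0 fell (11 adjusted over the list alone; list adjusted p = 1.06e-14), HSP10 (1.60 ± 0.22) and CPR6 (1.63 ± 0.24) included, while HSP104 did not pass (-0.14 ± 0.29, adjusted p = 0.862). Oxidative stress defence rose at 8 of 28 genes (14 adjusted over the list alone; list adjusted p = 2.87e-08), with AHP1 at 2.33 ± 0.25, TSA1 at 1.56 ± 0.24 and TRX2 at 1.48 ± 0.25.

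Of 15 glycolysis genes 8 rose and 1 fell in SM1 (10 and 1 adjusted over the list alone; list adjusted p = 2.87e-08), with TDH1 at 1.76 ± 0.27, GPM1 at 1.73 ± 0.27 and TDH3 at 1.71 ± 0.27. Fatty acid and phospholipid genes rose at 3 of 20 (5 adjusted over the list alone; list adjusted p = 0.000547), among them OPI3, a phospholipid methyltransferase (3.88 ± 0.39), and ACC1, acetyl-CoA carboxylase (2.24 ± 0.20). The carbonic anhydrase gene NCE103 rose by 2.96 ± 0.33. STE2 (-2.10 ± 0.35) and the glycerol-3-phosphate dehydrogenase gene GPD1 (-1.01 ± 0.25) fell. The ribosomal protein list had a median of only -0.16, with 1 of 136 genes up, RPL9B (1.33 ± 0.18), and 0 down (the same counts adjusted over the list alone); its call was lost (adjusted p = 0.466 with an estimated correlation). Ergosterol genes fell at 5 of 24 (7 adjusted over the list alone), HMG1 at -1.95 ± 0.31 and ERG2 at -1.28 ± 0.28 among them, also without a call once the correlation was estimated (adjusted p = 0.0691 with an estimated correlation). OLE1 (0.08 ± 0.48, adjusted p = 0.953), TPS1 (0.04 ± 0.31, adjusted p = 0.970), ADH1 (0.60 ± 0.32, adjusted p = 0.356), ADH2 (0.29 ± 0.32, adjusted p = 0.707) and PMA1 (-0.68 ± 0.46, adjusted p = 0.484) did not pass in SM1.

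In SM1 231 genes passed, 160 higher and 71 lower with ethanol. Other calls were not kept with an estimated correlation. Cell wall integrity had 4 of 22 up, PIR3 (2.28 ± 0.26) and TIP1 (2.36 ± 0.27) included, with 6 up and 3 down adjusted over the list alone (adjusted p = 0.0576 with an estimated correlation). Sulfur assimilation had 3 of 23 down, MUP1 (-1.63 ± 0.31) and MET10 (-1.74 ± 0.41) included, with 5 down adjusted over the list alone (adjusted p = 0.262 with an estimated correlation). Mitochondrial ribosomal proteins had 3 of 69 up, with 5 adjusted over the list alone (adjusted p = 0.0713 with an estimated correlation). Ethanol and acetaldehyde metabolism had 2 up and 1 down of 18, the same adjusted over the list alone, PDC1, pyruvate decarboxylase, at -1.07 ± 0.27 (adjusted p = 0.191 with an estimated correlation). The count fell to 112 without the dye term and to between 113 and 124 without any single SM1 array grown without ethanol. It rose to 476 with quantile normalization (288 higher, 188 lower) and to 799 with array weights (500 higher, 299 lower).

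In CM1 glycolysis and general stress genes had the highest list medians with ethanol. Of 15 glycolysis genes 11 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 2.16 and list adjusted p = 9.46e-31, TDH3 at 2.88 ± 0.27, TDH1 at 2.67 ± 0.27 and ENO2 at 2.55 ± 0.27. Of 30 Msn2/4 genes 15 rose and 0 fell (21 adjusted over the list alone; list adjusted p = 4.7e-27), including YGP1, a cell wall related glycoprotein of nutrient stress (3.69 ± 0.22), DDR2 (3.62 ± 0.23), SPI1 (2.26 ± 0.22) and HOR7 (2.03 ± 0.23). HSP12 rose by 4.11 ± 0.54, HSP26 by 2.80 ± 0.46, HSP31 by 2.02 ± 0.23 and the chaperonin gene HSP60 by 1.52 ± 0.22, and 8 of 27 chaperone genes rose in all (13 adjusted over the list alone; list adjusted p = 1.3e-10). HSP104 (0.86 ± 0.29, adjusted p = 0.1) and CTT1 (0.34 ± 0.39, adjusted p = 0.670) did not pass. Cell wall integrity rose at 7 of 22 genes (11 up and 1 down adjusted over the list alone; list adjusted p = 7.03e-10), with PIR3 at 3.44 ± 0.26 and CWP1 at 1.95 ± 0.25. THI6, of thiamine synthesis, rose by 4.14 ± 0.57, GIT1 by 3.37 ± 0.48 and NCE103 by 2.90 ± 0.33.

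Storage and respiratory genes rose too in CM1. Trehalose and glycogen metabolism had 5 of 21 up (11 adjusted over the list alone; list adjusted p = 9e-06), the glycogen synthase gene GSY2 at 1.54 ± 0.27 and PGM2 at 1.46 ± 0.26, although TPS1 did not pass (0.23 ± 0.31, adjusted p = 0.721). Ethanol and acetaldehyde metabolism had 5 up and 1 down of 18 (7 and 2 adjusted over the list alone; list adjusted p = 5.85e-05), with ALD4 at 3.01 ± 0.28, ALD6 at 2.07 ± 0.25, ADH2 at 1.96 ± 0.32 and ADH1 at 1.38 ± 0.32. The TCA and glyoxylate cycles had 5 up and 1 down of 23 (6 and 1 adjusted over the list alone; list adjusted p = 0.00105), with the isocitrate dehydrogenase gene IDH2 at 2.04 ± 0.21. Mitochondrial ribosomal proteins rose at 9 of 69 (21 adjusted over the list alone; list adjusted p = 7.03e-10), MRPL49 at 1.39 ± 0.22. Nuclear respiratory genes rose at 4 of 40 (6 adjusted over the list alone; list adjusted p = 7.01e-05). Oxidative stress defence rose at 6 of 28 (10 adjusted over the list alone; list adjusted p = 1.58e-06), AHP1 at 3.43 ± 0.25 and the superoxide dismutase gene SOD1 at 0.99 ± 0.18. Vacuolar genes rose at 4 of 21 (4 adjusted over the list alone; list adjusted p = 0.0174).

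Fewer groups went down in CM1 with ethanol. Histones and S-phase genes fell at 6 of 26 (9 adjusted over the list alone; list adjusted p = 5.86e-08), with the histone genes HTB2 at -2.67 ± 0.29, HTA2 at -2.24 ± 0.24 and HHF2 at -1.83 ± 0.25. Ribosomal proteins fell at 11 of 136 (22 down and 1 up adjusted over the list alone; median -0.41, list adjusted p = 8.35e-13), RPL22B at -1.79 ± 0.20, and ribosome biogenesis at 7 of 66 (11 adjusted over the list alone; list adjusted p = 4.5e-09), NOG2 at -0.92 ± 0.21. OLE1 (-2.03 ± 0.48), FET3 (-2.29 ± 0.52), the leucine gene LEU1 (-2.01 ± 0.22) and the methionine permease gene MUP1 (-2.08 ± 0.31) fell. GPD1 (-0.31 ± 0.25, adjusted p = 0.527) and PMA1 (0.24 ± 0.46, adjusted p = 0.820) did not pass. Lists called but not kept were glycerol metabolism with 1 of 12 up (4 adjusted over the list alone; adjusted p = 0.0645 with an estimated correlation). So were the proteasome with 1 of 32 up (0 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation) and sulfur assimilation with 1 of 23 down (3 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation). In CM1 317 genes passed, 219 higher and 98 lower. A fit to the 6 CM1 arrays alone called 19 genes, 18 higher and 1 lower, and array weights gave 602 (374 higher, 228 lower). The count was 142 without the dye term and between 141 and 169 without any single CM1 array grown without ethanol.

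**Figure D1:**
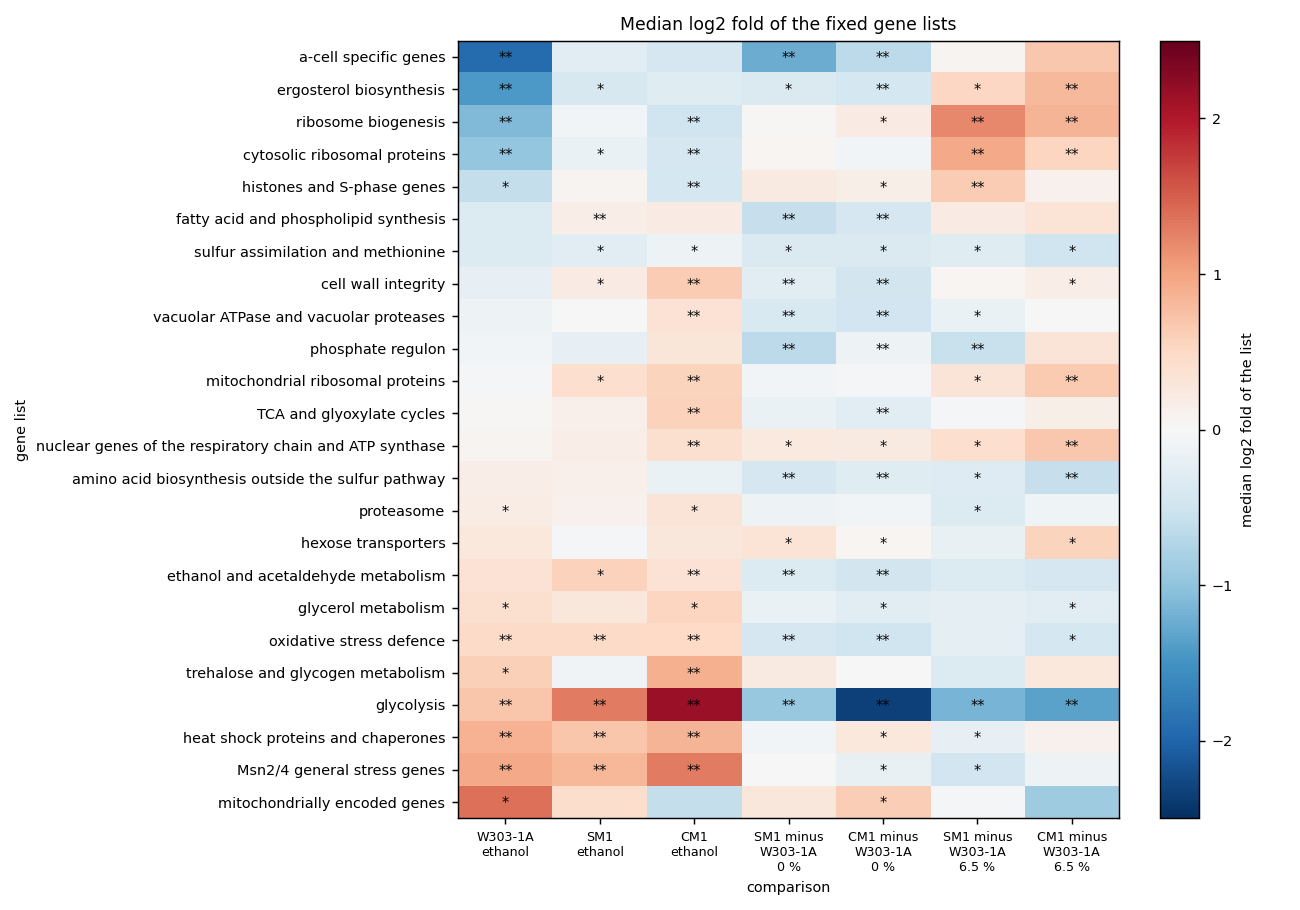
Median log2 fold (colour) of each fixed gene list called in at least 1 of the comparisons shown, by comparison (columns: ethanol response of each strain, then mutant minus W303-1A at 0 and 6.5 % v/v ethanol). A star marks a list called with the preset correlation of 0.01 and a double star one also called with an estimated correlation; the glycolysis median was 2.16 in CM1 with ethanol and -2.33 in CM1 against W303-1A without ethanol.

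Without ethanol, the question was how SM1 differed from its parent at rest. SM1 had lower lipid, phosphate, glycolytic and mating transcripts. OLE1 was lower by a log2 difference of -2.82 ± 0.48, and the repressible acid phosphatase genes PHO5 (-2.43 ± 0.26), PHO11 (-2.51 ± 0.29) and PHO12 (-2.5 ± 0.31) and the phosphate transporter gene PHO84 (-2.29 ± 0.36) were lower as well. The phosphate regulon fell at 5 of 15 genes (7 adjusted over the list alone; list adjusted p = 3.14e-13). Of 15 glycolysis genes 7 were lower and 0 higher (10 lower adjusted over the list alone; median -0.96, list adjusted p = 7.71e-17), with TDH3 at -2.34 ± 0.27, ENO2 at -1.48 ± 0.27, ENO1 at -1.46 ± 0.27 and TDH2 at -1.18 ± 0.19. Fatty acid and phospholipid genes were lower at 5 of 20 (8 adjusted over the list alone; list adjusted p = 3.24e-08), among them FAS2 (-1.74 ± 0.28), FAA4 (-1.46 ± 0.30) and ACC1 (-1.23 ± 0.20). The a-cell genes were lower at 3 of 7 (4 adjusted over the list alone; list adjusted p = 9.97e-09), BAR1 at -2.27 ± 0.48, STE2 at -1.54 ± 0.35 and MFA2 at -1.24 ± 0.19.

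Amino acid synthesis was lower in SM1 at 3 of 45 genes (7 adjusted over the list alone; list adjusted p = 3.71e-05), ARG4 (-2.15 ± 0.22) and HIS4 (-2.01 ± 0.44) included. Cell wall integrity was lower at 3 of 22 (5 adjusted over the list alone; list adjusted p = 7.29e-05), CWP1 at -2.23 ± 0.25. Vacuolar genes were lower at 3 of 21 (6 lower and 1 higher adjusted over the list alone; list adjusted p = 7.36e-05), the protease gene PEP4 at -1.19 ± 0.21. Oxidative stress defence was lower at 2 of 28 (6 adjusted over the list alone; list adjusted p = 7.36e-05). Ethanol and acetaldehyde metabolism was called lower with 0 of 18 members past the threshold (0 adjusted over the list alone; list adjusted p = 0.00341). YGP1 (-2.20 ± 0.22), the copper transporter gene CTR1 (-2.25 ± 0.26) and FET3 (-2.22 ± 0.52) were lower, as was YML039W, an open reading frame of a Ty retrotransposon (-2.28 ± 0.25). The genes that stood higher included CHA1 (2.64 ± 0.35), YKR075C (2.39 ± 0.38), the sodium pump gene ENA1 (2.07 ± 0.48) and NPL3, of mRNA export (1.62 ± 0.33). HSP12 (0.48 ± 0.54, adjusted p = 0.819) and HSP26 (0.08 ± 0.46, adjusted p = 0.971) did not pass. Lists called but not kept were ergosterol synthesis with 0 of 24 past the threshold (adjusted p = 0.0934 with an estimated correlation), nuclear respiratory genes with 0 of 40 (adjusted p = 0.101 with an estimated correlation). Neither were hexose transporters with 0 of 19 (adjusted p = 0.189 with an estimated correlation) and sulfur assimilation with 1 of 23 lower (adjusted p = 0.266 with an estimated correlation). Adjusted over the list alone these 4 were 1 lower, 0, 4 higher and 4 lower. In SM1 98 genes passed, 10 higher and 88 lower. Without SM1 replicate 2 grown without ethanol 32 passed, and without the dye term 34, while quantile normalization gave 303.

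For CM1 without ethanol, the glycolytic difference from W303-1A was the largest of any list in this comparison. Of 15 glycolysis genes 11 were lower and 0 higher (13 adjusted over the list alone), with a median of -2.33 and list adjusted p = 3.73e-72. TDH3 stood at -3.14 ± 0.27, the pyruvate kinase gene CDC19 at -2.95 ± 0.32, FBA1 at -2.81 ± 0.25, ENO2 at -2.69 ± 0.27, TDH2 at -2.65 ± 0.19, ENO1 at -2.59 ± 0.27 and GPM1 at -2.51 ± 0.27. The fermentation genes PDC1 (-2.26 ± 0.27), ADH1 (-2.20 ± 0.32), ADH2 (-2.20 ± 0.32) and ALD6 (-1.50 ± 0.25) were lower, 4 of 18 in their list (7 lower and 1 higher adjusted over the list alone; list adjusted p = 1.55e-07). Glycerol synthesis genes GPP1 (-1.93 ± 0.26) and GPD2 (-1.60 ± 0.34) were the 2 lower of 12 in theirs (3 adjusted over the list alone), a call that was lost (adjusted p = 0.0679 with an estimated correlation). Cell wall genes CWP1 (-2.86 ± 0.25) and PST1 (-1.84 ± 0.31) were among 3 lower of 22 (5 adjusted over the list alone; list adjusted p = 1.71e-08). PHO5 (-2.14 ± 0.26), PHO11 (-2.22 ± 0.29) and PHO12 (-2.18 ± 0.31) were among 4 lower of 15 phosphate genes (4 adjusted over the list alone; list adjusted p = 0.000106). YGP1 (-2.78 ± 0.22) and BAR1 (-2.56 ± 0.48) were lower too. YKR075C (2.74 ± 0.38), BTN2 (1.54 ± 0.30) and the vacuolar calcium pump gene PMC1 (1.46 ± 0.32) stood higher.

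Smaller shifts of the same sign in CM1 without ethanol ran through the TCA and glyoxylate cycles at 3 of 23 (3 adjusted over the list alone; list adjusted p = 0.0277), IDH2 at -1.51 ± 0.21. They included vacuolar genes at 3 of 21 (4 lower and 1 higher adjusted over the list alone; list adjusted p = 0.000484) and a-cell genes at 1 of 7 (4 adjusted over the list alone; list adjusted p = 0.000106). Oxidative stress defence was lower at 1 of 28 (6 adjusted over the list alone; list adjusted p = 0.000299). Fatty acid and phospholipid synthesis was lower at 1 of 20 (4 adjusted over the list alone; list adjusted p = 0.0019) and amino acid synthesis at 1 of 45 (3 adjusted over the list alone; list adjusted p = 0.00211). Ergosterol synthesis was called lower with 0 of 24 past the threshold (6 adjusted over the list alone; list adjusted p = 2.66e-06). Calls not kept were ribosome biogenesis (higher, 0 of 66 and 0 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation) and chaperones (1 of 27 higher, 1 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation). Also lost were nuclear respiratory genes (higher, 0 of 40 and 0 adjusted over the list alone; adjusted p = 0.190 with an estimated correlation) and sulfur assimilation (lower, 0 of 23 and 2 adjusted over the list alone; adjusted p = 0.199 with an estimated correlation). The Msn2/4 genes (2 of 30 lower, 5 lower and 2 higher adjusted over the list alone; adjusted p = 0.206 with an estimated correlation) and mitochondrially encoded genes (higher, 0 of 8 and 0 adjusted over the list alone; adjusted p = 0.398 with an estimated correlation) lost their calls. So did histones and S-phase genes (higher, 0 of 26, with 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.147 with an estimated correlation) and hexose transporters (higher, 0 of 19 and 3 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). HSP12 (-0.28 ± 0.54, adjusted p = 0.908), HSP26 (-0.12 ± 0.46, adjusted p = 0.965) and OLE1 (-0.77 ± 0.48, adjusted p = 0.586) did not pass. In CM1 69 genes passed, 6 higher and 63 lower. Without CM1 replicate 3 grown without ethanol 38 passed, and without the dye term 42, while quantile normalization gave 261.

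Between the mutants without ethanol, CM1 stood lower than SM1 at glycolysis. Of 15 glycolysis genes 6 were lower in CM1 and 0 higher (12 lower adjusted over the list alone; median -0.95, list adjusted p = 3.9e-37), with FBA1 at -1.86 ± 0.25, GPM1 at -1.58 ± 0.27 and TDH2 at -1.47 ± 0.19, and GPP1 (-1.70 ± 0.26) and ADH1 (-1.50 ± 0.32) were lower. The largest rises among the named genes were YDR316W-A (2.97 ± 0.63), YGR161C-C (2.76 ± 0.52) and YMR051C (2.64 ± 0.55), with YER138C at 2.34 ± 0.44. These are open reading frames of Ty retrotransposons, repeated elements that read each other, so they are not separate observations, and Ty elements were not tested as a list. The chaperone list was called higher at 2 of 27 genes (3 adjusted over the list alone; list adjusted p = 3.26e-08), BTN2 (1.84 ± 0.30) and HSP31 (1.11 ± 0.23), and the phosphate regulon at 1 of 15 (2 adjusted over the list alone; list adjusted p = 0.000148), SPL2 (1.60 ± 0.32). Ethanol and acetaldehyde metabolism was called lower at 2 of 18 (4 lower and 1 higher adjusted over the list alone; list adjusted p = 0.00357). Glycerol metabolism was called lower at 1 of 12 (1 adjusted over the list alone; list adjusted p = 0.0056), and fatty acid and phospholipid synthesis higher at 1 of 20 (4 adjusted over the list alone; list adjusted p = 0.00762). PHO84 (1.57 ± 0.36, adjusted p = 0.0556) and OLE1 (2.05 ± 0.48, adjusted p = 0.0583) did not pass. In this contrast 9 lists were called and 6 kept with an estimated correlation, and 57 genes passed, 46 higher and 11 lower in CM1. With the normal dye orientation alone limma called 0 genes (269 at an unadjusted p under 0.05), and without SM1 replicate 1 grown without ethanol 7 did.

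With ethanol, SM1 held higher ribosomal transcripts than W303-1A. Of 136 ribosomal protein genes 92 were higher and 0 lower (103 adjusted over the list alone; median 0.94, list adjusted p = 1.63e-32), among them RPL6B (2.00 ± 0.24), RPS1B (1.95 ± 0.23) and RPS11B (1.81 ± 0.21). Ribosome biogenesis was higher at 45 of 66 genes (54 adjusted over the list alone; median 1.21, list adjusted p = 7.46e-24), with NSR1 at 3.19 ± 0.50, RPA190 at 2.38 ± 0.29 and HAS1 at 2.27 ± 0.30, and DBP2 stood at 3.91 ± 0.34. Histones and S-phase genes were higher at 11 of 26 (13 adjusted over the list alone; list adjusted p = 1.03e-05), including the G1 cyclin gene CLN2 (2.89 ± 0.31), HHF2 (1.68 ± 0.25) and the DNA polymerase gene POL1 (1.46 ± 0.22). Glycolysis was lower at 9 of 15 genes (12 adjusted over the list alone; median -1.16, list adjusted p = 7.12e-15), with ENO2 at -2.80 ± 0.27, ENO1 at -2.79 ± 0.27, TDH1 at -2.38 ± 0.27 and TDH2 at -1.85 ± 0.19. The largest differences were ANS1 (7.08 ± 0.77), NCA3 (6.02 ± 0.79) and SIP18 (4.74 ± 0.52), all higher in SM1.

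Several stress genes were lower in SM1 than in the parent under ethanol, HSP26 (-2.76 ± 0.46), HSP12 (-2.29 ± 0.54), HSP31 (-2.08 ± 0.23) and SSA1 (-1.95 ± 0.34) among them. The chaperone list fell at 7 of 27 (9 lower and 1 higher adjusted over the list alone), a call that was lost (adjusted p = 0.253 with an estimated correlation). CTT1 was higher (1.23 ± 0.39). ADH2 (-2.24 ± 0.32) and ADH1 (-1.77 ± 0.32), HIS4 (-3.02 ± 0.44), ARG4 (-2.60 ± 0.22), the cytochrome c isoform gene CYC7 (-2.91 ± 0.29) and the cell wall gene HSP150 (-2.83 ± 0.42) were lower. The phosphate regulon was lower at 6 of 15 and higher at 1 (8 and 1 adjusted over the list alone; list adjusted p = 0.00383), with SPL2 at -1.87 ± 0.32, PHO5 at -1.32 ± 0.26 and GIT1 at 1.95 ± 0.48. Calls not kept were the proteasome (8 of 32 lower, 9 adjusted over the list alone; adjusted p = 0.225 with an estimated correlation) and ergosterol synthesis (7 of 24 higher, 1 lower, 9 and 1 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation). Amino acid synthesis (12 of 45 lower, 4 higher, 14 and 4 adjusted over the list alone; adjusted p = 0.0689 with an estimated correlation) and nuclear respiratory genes (12 of 40 higher, 2 lower, 14 and 3 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation) were lost too. So were mitochondrial ribosomal proteins (9 of 69 higher, 8 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation) and Msn2/4 genes (8 of 30 lower, 3 higher, 10 and 4 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation). The last were sulfur assimilation (5 of 23 lower, 1 higher, 6 and 1 adjusted over the list alone; adjusted p = 0.265 with an estimated correlation) and vacuolar genes (4 of 21 lower, 4 adjusted over the list alone; adjusted p = 0.179 with an estimated correlation). In this contrast 989 genes passed, 583 higher and 406 lower in SM1. The count was 511 without the dye term, 552 with quantile normalization and 574 in a fit to the 6 arrays compared.

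CM1 under ethanol differed from W303-1A at glycolysis and ribosome synthesis among other groups. The hexose transporter genes HXT4 (4.83 ± 0.50), HXT3 (3.00 ± 0.31) and HXT2 (1.55 ± 0.29) were among 4 of 19 higher, with 1 lower (6 and 1 adjusted over the list alone), though the list's call was lost (adjusted p = 0.0975 with an estimated correlation). Glycolysis was lower at 9 of 15 genes (11 adjusted over the list alone; median -1.34, list adjusted p = 1.32e-20), with ENO1 at -3.14 ± 0.27, TDH2 at -2.76 ± 0.19 and PGK1 at -2.74 ± 0.25, and ADH1 stood at -2.49 ± 0.32. HSP12 (-3.94 ± 0.54) and HSP26 (-3.03 ± 0.46) were lower than in the parent. Ribosome biogenesis was higher at 27 of 66 (41 adjusted over the list alone; list adjusted p = 2.48e-16), HAS1 at 2.27 ± 0.30 and RRP5 at 1.93 ± 0.29. Ribosomal proteins were higher at 39 of 136 with 1 lower (53 and 1 adjusted over the list alone; median 0.54, list adjusted p = 1.32e-11), RPL6B at 1.43 ± 0.24 and RPS11A at 1.30 ± 0.20. Ergosterol synthesis was higher at 9 of 24 with 1 lower (13 and 1 adjusted over the list alone; list adjusted p = 4.46e-07), ERG3 at 1.98 ± 0.27 and ERG25 at 1.63 ± 0.31.

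Mitochondrial genes of the nucleus were higher in CM1 under ethanol. The respiratory list had 12 higher and 1 lower of 40 (19 and 2 adjusted over the list alone; list adjusted p = 6.94e-06), the external NADH dehydrogenase gene NDE1 at 2.24 ± 0.25 and SDH2 at 1.71 ± 0.25. Mitochondrial ribosomal proteins had 19 of 69 higher (27 adjusted over the list alone; list adjusted p = 1.02e-07), MRPL10 at 1.21 ± 0.20. The mitochondrially encoded list was not called (adjusted p = 0.0578), with 1 of 8 lower (1 adjusted over the list alone), COX3 (-2.27 ± 0.65). Amino acid synthesis was lower at 13 of 45 with 2 higher (17 and 3 adjusted over the list alone; list adjusted p = 1.03e-06), HIS4 at -3.65 ± 0.44, LYS21 at -3.09 ± 0.24 and ARG4 at -2.86 ± 0.22, and the general amino acid permease gene GAP1 stood at -3.69 ± 0.60. DBP2 (3.93 ± 0.34), GUA1 (2.47 ± 0.32), ALD6 (2.46 ± 0.25) and the cell wall gene CIS3 (2.28 ± 0.22) were higher, and ACB1, the acyl-CoA binding protein, was lower (-3.44 ± 0.32). Calls not kept were cell wall integrity (5 of 22 higher, 1 lower, the same adjusted over the list alone; adjusted p = 0.106 with an estimated correlation) and oxidative stress defence (4 of 28 lower, 7 lower and 2 higher adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). Nor were glycerol metabolism (2 of 12 lower, 3 adjusted over the list alone; adjusted p = 0.146 with an estimated correlation) and sulfur assimilation (4 of 23 lower, 1 higher, the same adjusted over the list alone; adjusted p = 0.334 with an estimated correlation). In this contrast 692 genes passed, 393 higher and 299 lower in CM1. A fit to the 6 arrays compared called 40, 18 higher and 22 lower, quantile normalization gave 185, and without CM1 replicate 1 grown with ethanol 1048 passed.

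Between the mutants under ethanol, CM1 had higher THI6 (4.91 ± 0.57), HXT4 (2.45 ± 0.50), HXT3 (2.04 ± 0.31) and the zinc transporter gene ZRT1 (2.07 ± 0.21). The phosphate regulon was higher at 4 of 15 genes (7 adjusted over the list alone; list adjusted p = 4.89e-07), SPL2 at 2.08 ± 0.32, PHO5 at 1.97 ± 0.26 and PHO12 at 1.83 ± 0.31. ANS1 (-6.31 ± 0.77) and SIP18 (-5.18 ± 0.52) were lower in CM1. Histones and S-phase genes were lower at 6 of 26 (11 adjusted over the list alone; list adjusted p = 6.56e-09), with CLN2 at -2.01 ± 0.31, HTB2 at -1.98 ± 0.29 and HHF2 at -1.65 ± 0.25. Ribosomal proteins were lower at 6 of 136 (24 adjusted over the list alone; list adjusted p = 2.94e-12), RPL21A at -1.45 ± 0.32 and RPS19B at -0.94 ± 0.19. HSP104 (1.36 ± 0.29) and HSP60 (1.07 ± 0.22) were higher and CTT1 lower (-1.58 ± 0.39). Trehalose and glycogen metabolism was called higher with 0 of 21 past the threshold (6 adjusted over the list alone; list adjusted p = 0.000423), TSL1 at 1.11 ± 0.29 (adjusted p = 0.0534). In this contrast 14 lists were called and 4 kept with an estimated correlation, and 138 genes passed, 72 higher and 66 lower in CM1. A limma fit to the 6 arrays compared called 0 (603 at an unadjusted p under 0.05), with 18 called without the dye term. The balance moved with the method, to 17 higher and 23 lower with quantile normalization, 172 and 100 with the normal dye orientation alone, and 88 and 92 without CM1 replicate 2 grown with ethanol.

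The test of the difference between ethanol responses asked whether a mutant answered ethanol otherwise than its parent. For SM1 minus W303-1A ribosomal, lipid and a-cell genes were among those that differed. Of 136 ribosomal protein genes 28 had a more positive response in SM1 and 0 a more negative one (71 adjusted over the list alone; median 0.82, list adjusted p = 2.01e-20), with RPL6B at 2.19 ± 0.34 and RPS1B at 1.96 ± 0.32. Ribosome biogenesis was more positive at 24 of 66 (38 adjusted over the list alone; median 1.17, list adjusted p = 1.69e-16), HAS1 at 2.83 ± 0.43 and RPA190 at 2.26 ± 0.41, with DBP2 at 4.28 ± 0.48. Fatty acid and phospholipid genes were more positive at 4 of 20 (8 adjusted over the list alone; median 0.87, list adjusted p = 8.55e-05), ACC1 at 3.61 ± 0.28, OLE1 at 3.56 ± 0.68 and FAS2 at 2.52 ± 0.39. Ergosterol genes were so at 7 of 24 (17 with 1 negative adjusted over the list alone; median 1.02, list adjusted p = 4.89e-07), ERG3 at 2.64 ± 0.38 and ERG25 at 1.80 ± 0.44. Histones and S-phase genes were so at 5 of 26 (9 adjusted over the list alone; median 0.42, list adjusted p = 0.00226), CLN2 at 4.32 ± 0.44. The a-cell genes were so at 3 of 7 (5 adjusted over the list alone; median 1.31, list adjusted p = 0.0035), BAR1 at 2.76 ± 0.68. ANS1 (6.49 ± 1.10), SIP18 (4.52 ± 0.74), YGP1 (2.79 ± 0.31) and CTT1 (2.42 ± 0.56) were more positive. CHA1 (-4.46 ± 0.49), ARO10, of amino acid catabolism (-3.83 ± 0.49), CYC7 (-3.68 ± 0.41), HSP26 (-2.85 ± 0.65), HSP12 (-2.77 ± 0.76) and SSA1 (-2.18 ± 0.48) were more negative in SM1. Calls not kept were cell wall integrity with 3 of 22 more positive and 1 more negative (6 and 2 adjusted over the list alone, median 0.36, adjusted p = 0.0671 with an estimated correlation) and trehalose and glycogen metabolism with 2 of 21 more negative (4 adjusted over the list alone, median -0.36, adjusted p = 0.0939 with an estimated correlation). Mitochondrial ribosomal proteins with 5 of 69 more positive (5 adjusted over the list alone, median 0.44, adjusted p = 0.349 with an estimated correlation) lost their call too. In all, 360 genes passed, 257 more positive and 103 more negative. Without SM1 replicate 2 grown without ethanol 151 passed, and without the dye term 106, while array weights gave 870.

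For CM1 minus W303-1A, ergosterol genes were more positive at 11 of 24 (17 with 1 negative adjusted over the list alone; median 1.21, list adjusted p = 3.32e-12), with ERG3 at 3.02 ± 0.38 and ERG11 at 2.20 ± 0.35. Cell wall genes were more positive at 8 of 22 (9 adjusted over the list alone; median 0.76, list adjusted p = 2.58e-07), CWP1 at 2.77 ± 0.35 and CIS3 at 2.73 ± 0.32. The phosphate regulon had 3 of 15 more positive and 1 more negative (4 and 1 adjusted over the list alone; median 0.46, list adjusted p = 0.00759), PHO12 at 3.03 ± 0.44 and PHO5 at 2.79 ± 0.37. The a-cell genes were more positive at 3 of 7 (3 adjusted over the list alone; median 1.29, list adjusted p = 0.000123), BAR1 at 3.87 ± 0.68 and STE2 at 2.91 ± 0.50. Fatty acid and phospholipid synthesis had 3 of 20 more positive and 1 more negative (6 and 1 adjusted over the list alone; median 0.89, list adjusted p = 0.00897). YGP1 (4.37 ± 0.31), DBP2 (4.13 ± 0.48), ALD6 (3.96 ± 0.36), HXT4 (3.53 ± 0.71), TDH3 (2.35 ± 0.38) and CDC19 (1.99 ± 0.46) were more positive. HSP12 (-3.66 ± 0.76), CHA1 (-3.10 ± 0.49), HSP26 (-2.91 ± 0.65), CYC7 (-2.59 ± 0.41), HTB2 (-2.07 ± 0.41), SSA1 (-2.06 ± 0.48) and HSP31 (-1.59 ± 0.33) were more negative. Ribosomal proteins were more positive at 13 of 136 with 1 more negative (23 and 1 adjusted over the list alone; median 0.60), RPL6B at 1.81 ± 0.34 and RPL22B at -1.76 ± 0.28, but the call was lost (adjusted p = 0.0845 with an estimated correlation). The same was true of ribosome biogenesis at 7 of 66 (16 adjusted over the list alone; median 0.69), HAS1 at 2.62 ± 0.43 (adjusted p = 0.101 with an estimated correlation). It was true too of mitochondrial ribosomal proteins at 11 of 69 (16 with 1 negative adjusted over the list alone, median 0.58, adjusted p = 0.0528 with an estimated correlation) and chaperones at 4 of 27 more negative (5 with 1 positive adjusted over the list alone, median -0.25, adjusted p = 0.393 with an estimated correlation). The mitochondrially encoded genes had the most negative median of the called lists, -1.60, with 0 of 8 past the threshold (0 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). Amino acid synthesis had 4 of 45 more negative and 1 more positive (10 and 3 adjusted over the list alone, median -0.16, adjusted p = 0.216 with an estimated correlation). Nuclear respiratory genes had 4 of 40 more positive and 1 more negative (7 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.35 with an estimated correlation). In all, 263 genes passed, 195 more positive and 68 more negative. With the trend along the probe number removed 163 passed, without CM1 replicate 3 grown without ethanol 98, and without CM1 replicate 1 grown with ethanol 577.

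For CM1 minus SM1 few single genes differed. THI6 (4.79 ± 0.81), SHM2 (1.86 ± 0.32), ZRT1 (1.64 ± 0.29) and YGP1 (1.58 ± 0.31) responded more positively in CM1. ANS1 (-6.08 ± 1.10), SIP18 (-4.88 ± 0.74), ISU2, of iron-sulfur assembly (-2.94 ± 0.32), the leucine genes LEU2 (-2.75 ± 0.45) and LEU1 (-1.98 ± 0.31), CLN2 (-2.38 ± 0.44) and ALD5 (-2.15 ± 0.35) responded more negatively. Histones and S-phase genes were more negative at 4 of 26 (11 adjusted over the list alone; median -0.53, list adjusted p = 1.77e-09), HTB2 at -2.54 ± 0.41 and HHF2 at -2.17 ± 0.35. Glycolysis (median 0.91, list adjusted p = 1.77e-09) and trehalose and glycogen metabolism (median 0.75, list adjusted p = 1.02e-05) were called more positive with 0 members past the threshold, and with 6 of 15 and 5 of 21 adjusted over the list alone. Cell wall integrity (median 0.39, list adjusted p = 0.000726), the phosphate regulon (median 0.48, list adjusted p = 0.0302) and the TCA and glyoxylate cycles (median 0.19, list adjusted p = 0.0301) were also called more positive with 0 members past the threshold, and with 4 of 22, 2 of 15 and 2 of 23 adjusted over the list alone. Of 16 lists called, 6 were kept with an estimated correlation. In all, 19 genes passed, 6 more positive and 13 more negative, but array weights turned that balance, with 45 more positive and 30 more negative. Without SM1 replicate 2 or SM1 replicate 3 grown without ethanol 1 gene passed.

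**Figure D2:**
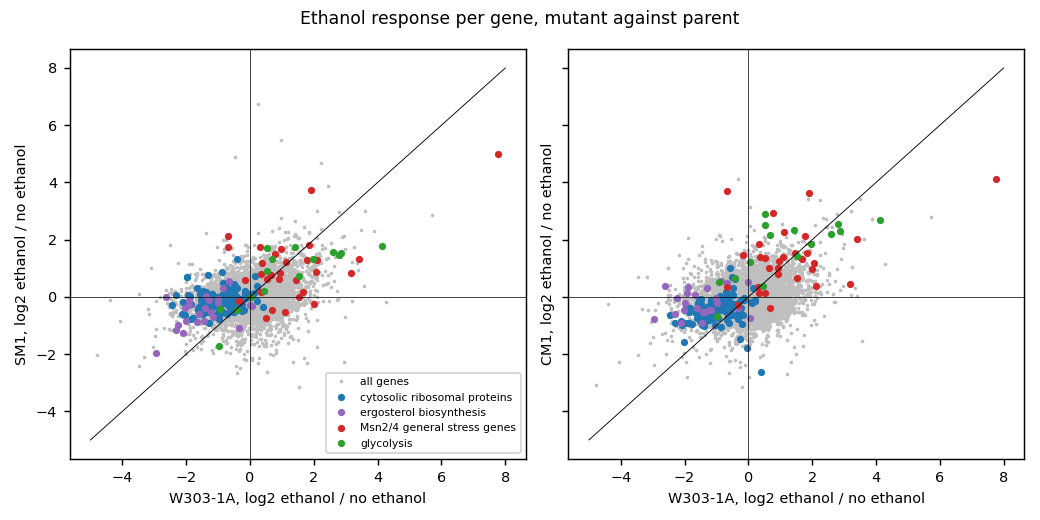
Log2 ethanol response of each of 5650 genes (points) in SM1 (left) and CM1 (right) against that in W303-1A, with 4 gene lists coloured and the line of equality drawn. Ribosomal proteins (blue) had a median of -0.97 in W303-1A, -0.16 in SM1 and -0.41 in CM1.

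Across genes, which are not independent replicates, the ethanol responses of W303-1A and SM1 had Pearson r = 0.317 (SE 0.14 from a jackknife over arrays) and Spearman rho = 0.272. Those of W303-1A and CM1 had r = 0.323 (jackknife SE 0.226) and rho = 0.266, and those of the mutants r = 0.365 (jackknife SE 0.132) and rho = 0.327. The slope on W303-1A was 0.227 for SM1 and 0.238 for CM1, and the slope of CM1 on SM1 was 0.376, values that the low r holds below 1 and that do not measure the size of a response. W303-1A and SM1 shared 86 genes called higher (16.4 by chance) and 34 called lower (9.69 by chance), with 13 called in opposite directions. W303-1A and CM1 shared 99 higher (22.4 by chance) and 61 lower (13.4 by chance), with 13 opposite. SM1 and CM1 shared 75 higher (6.20 by chance) and 8 lower (1.23 by chance), with 2 opposite. In all 3 strains 51 genes rose, HSP12, HSP26, HSP31, HSP10, DDR2, AHP1, TRX2, TDH1, ENO1, PGK1 and ALD4 among them, and 7 fell, MUP1 among them.

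The mutants were compared with the same 3 W303-1A arrays, so part of the likeness of those contrasts may come from shared controls, and 3 arrays cannot be split into separate control sets of at least 2. Without ethanol the SM1 and CM1 differences had r = 0.690 and covariance 0.176 across genes, against 0.499 and 0.0788 for simulated unchanged mutants. With ethanol they had r = 0.637 and covariance 0.371, against 0.5 and 0.0788. Brackets give the count if independent, then the mean and highest count of as many top-ranked genes in 100 simulated sets that share the controls. Both mutants were lower at 34 of the same genes without ethanol (0.981, 10.51 and 19). Both were higher at 2 (0.0106, 0.4 and 3), which shared controls alone can give. With ethanol they were both higher at 259 (40.6, 143.1 and 165) and both lower at 151 (21.5, 92.6 and 109). The response differences from W303-1A had r = 0.685 and covariance 0.555, against 0.499 and 0.157. Of their genes 116 were more positive in both (8.87, 49.2 and 62) and 31 more negative (1.24, 12.7 and 21). Errors shared across genes, such as the trend along the probe number, were not tested as a source of overlap. An r or count above the simulated ones therefore does not exclude shared controls.

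Chromosomes were compared because a gained copy would raise all genes of one chromosome. Median differences lay between -0.26 on chromosome 16 and 0.17 on chromosome 2 for SM1 without ethanol, and between -0.27 on chromosome 16 and 0.16 on chromosome 4 for CM1. With ethanol they lay between -0.44 on chromosome 3 and 0.31 on chromosome 16 for SM1, and between -0.71 on chromosome 1 and 0.38 on chromosome 16 for CM1. The test called 5 and 4 chromosomes without ethanol and 10 and 11 with ethanol. With an estimated correlation it called 0 in each of the 4 contrasts, and also 0 once a quadratic trend along the probe number was removed from each array, when the medians lay between -0.25 and 0.16.

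Markers of other cell types gave no call. W303-1A is a haploid a strain, and of 4 alpha-cell genes 0 passed in any of the 3 ethanol contrasts. The alpha-cell, haploid-specific, meiosis and sporulation, pentose phosphate, NAD, peroxisome and iron regulon lists were not called in any of the 12 comparisons.

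**Figure D3:**
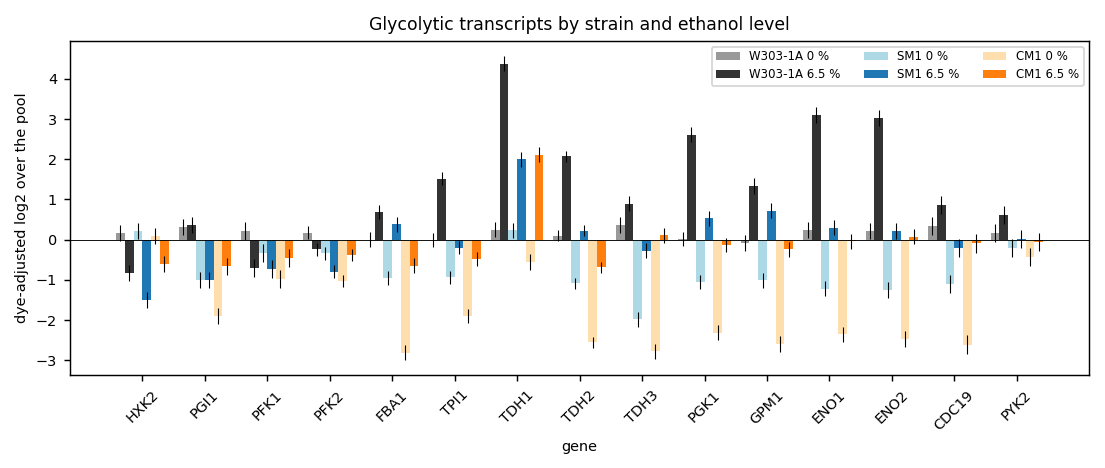
Dye-adjusted log2 level over the W303-1A pool (bars, ± limma standard error pooled over 18 arrays, n = 3 per group) of 15 glycolysis genes in the 6 groups. TDH3 stood at -1.98 in SM1 and -2.78 in CM1 without ethanol, and at 0.36 in W303-1A.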

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

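Tests chosen only after the result was seen were the second test of the ratio direction, on which the sign of the swapped arrays and so every result rests, those of the trend along the probe number, those of a single scale factor, and that of the glycolysis enzymes without a close copy. Results are listed here because the ethanol response differed between strains by a test of the difference itself.

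For SM1 minus W303-1A 360 genes passed. The genes named were RPL6B 2.19, RPS1B 1.96, HAS1 2.83, RPA190 2.26, DBP2 4.28, ERG3 2.64, ERG25 1.80, ACC1 3.61, OLE1 3.56, FAS2 2.52, CLN2 4.32, SIP18 4.52, ANS1 6.49, CTT1 2.42, YGP1 2.79, BAR1 2.76, CHA1 -4.46, CYC7 -3.68, ARO10 -3.83, HSP12 -2.77, HSP26 -2.85 and SSA1 -2.18. List medians were 0.82 for ribosomal proteins, 1.17 for ribosome biogenesis, 1.02 for ergosterol, 0.87 for fatty acids and phospholipids, 0.42 for histones and S-phase genes, 1.31 for a-cell genes, 0.36 for the cell wall, -0.36 for trehalose and glycogen metabolism and 0.44 for mitochondrial ribosomal proteins, the last 3 not called with an estimated correlation. Of 100 splits that exchanged strain labels within each ethanol level, 2 gave as many genes, the real one with 360 and another with 603. Such splits presume no difference between the strains at either ethanol level, and they took no account of dye orientation. They therefore cannot exclude chance for the response difference alone. The split with 603 kept the strains apart at both ethanol levels and exchanged them at one, so it measures the average strain difference, which points to a structure of the samples. The highest among splits that mixed the strains was 350.

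For CM1 minus W303-1A 263 genes passed. The genes named were ERG3 3.02, ERG11 2.20, RPL6B 1.81, RPL22B -1.76, HAS1 2.62, DBP2 4.13, YGP1 4.37, ALD6 3.96, HXT4 3.53, BAR1 3.87, STE2 2.91, CWP1 2.77, CIS3 2.73, PHO5 2.79, PHO12 3.03, TDH3 2.35, CDC19 1.99, HSP12 -3.66, HSP26 -2.91, HSP31 -1.59, SSA1 -2.06, CHA1 -3.10, CYC7 -2.59 and HTB2 -2.07. List medians were 1.21 for ergosterol, 0.60 for ribosomal proteins, 0.76 for the cell wall, 0.69 for ribosome biogenesis, 0.58 for mitochondrial ribosomal proteins, 1.29 for a-cell genes, 0.46 for the phosphate regulon, 0.89 for fatty acids and phospholipids, -0.25 for chaperones, -1.60 for the mitochondrially encoded genes, 0.31 for nuclear respiratory genes and -0.16 for amino acid synthesis. Of these 12 lists, 5 were kept with an estimated correlation. Of 100 splits 2 gave as many genes, the real one with 263 and one with 296 that again kept the strains apart at both levels. As for SM1, the splits cannot exclude chance for the response difference alone. Splits that mixed the strains gave at most 100.

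For CM1 minus SM1 19 genes passed. The genes named were THI6 4.79, ZRT1 1.64, YGP1 1.58, SHM2 1.86, ANS1 -6.08, SIP18 -4.88, HTB2 -2.54, HHF2 -2.17, CLN2 -2.38, LEU1 -1.98, LEU2 -2.75, ISU2 -2.94 and ALD5 -2.15. List medians were -0.53 for histones and S-phase genes, 0.91 for glycolysis, 0.75 for trehalose and glycogen metabolism, 0.39 for the cell wall, 0.48 for the phosphate regulon and 0.19 for the TCA and glyoxylate cycles. Of 100 splits 1, the real one, gave as many, and the highest other gave 9. Here too the splits cannot exclude chance for the response difference alone.

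For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes. The real value and the highest other were 1349 and 0 for ethanol in W303-1A, 231 and 0 in SM1, 317 and 0 in CM1, 98 and 0 for SM1 against W303-1A without ethanol, 69 and 0 for CM1 against W303-1A, 57 and 0 for CM1 against SM1, 989 and 20 for SM1 against W303-1A with ethanol, 692 and 1 for CM1 against W303-1A, and 138 and 13 for CM1 against SM1.

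Values rose along the probe number, which follows the chromosome number (Spearman rho 0.994 over 5654 probes). A property of the sample RNA, such as an extra chromosome, would change sign with the dyes, yet red over green rose with the probe number on 18 of 18 arrays, the lowest of the correlations being 0.229, with 0.241 to 0.527 on swapped arrays and 0.229 to 0.561 on normal ones. This rests on the swapped columns being red over green, which is likely but not certain. Under either reading, the W303-1A arrays without ethanol, which hold the RNA of the pool itself, had 0.391, 0.542 and 0.561, so a property of the mutants is not the whole cause. A dye bias along the print or numbering order is a candidate explanation, found and tested on the same data, and its origin stays open.

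Across genes on average both mutants had a smaller ethanol response than W303-1A (SD of the response across genes 0.87 in W303-1A, 0.63 in SM1 and 0.64 in CM1), but not in every list, as the medians in W303-1A, SM1 and CM1 were 0.69, 1.31 and 2.16 for glycolysis, -0.02, 0.42 and 0.55 for mitochondrial ribosomal proteins, -0.21, 0.20 and 0.64 for the cell wall, and 0.03, 0.13 and 0.58 for the TCA and glyoxylate cycles. Noisier mutant arrays would not lower the covariance between independent replicate pairs, yet its highest ratio to that of W303-1A was 0.462 in SM1 and 0.392 in CM1 (0.6 and 0.542 with the trend along the probe number removed). A single scale factor for every gene is argued against, because the fraction of the W303-1A response kept by the Msn2/4 list exceeded that kept by ribosomal proteins by 0.655 in SM1 (jackknife SE 0.161) and by 0.599 in CM1 (jackknife SE 0.211). The fractions were 0.791 and 0.136 in SM1 and 1.06 and 0.459 in CM1, but single stress genes rose less in the mutants, with response differences of -2.77 and -3.66 for HSP12, -2.85 and -2.91 for HSP26, -2.18 and -2.06 for SSA1, and -1.59 for HSP31 in CM1. That the fall of ribosomal genes is weaker holds by the test of the difference in SM1 only, since in CM1 the list lost its call (adjusted p = 0.0845 with an estimated correlation), and growth rate, sampling time and the sign of the swapped CM1 array, where the covariance of replicates 1 and 2 was 0.00223 (0.0575 with the trend removed), stay open.

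Glycolytic transcripts were lower in both mutants without ethanol. On the W303-1A arrays without ethanol the glycolysis median over the pool was 0.18, against differences of -0.96 in SM1 and -2.33 in CM1. This argues against an offset of those arrays from the pool. The pool holds RNA of the same cultures, so the value would lie near 0 whatever their state. It therefore cannot tell whether the parent cultures themselves had unusually high glycolytic transcripts. A fall of a few genes read on the probes of their copies is also argued against, since the median of the enzymes without a close copy, PGI1, FBA1, TPI1, PGK1 and GPM1, was -0.96 in SM1 (array SE 0.142) and -2.33 in CM1. A lower glycolytic programme in the unstressed mutants may be biological, as a hypothesis from these -0.96 and -2.33 values. Different growth phase at sampling was not tested and stays open.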

How the results depend on the processing

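Trend removal, the fit without 2 doubted arrays and that with all probes were chosen after the data were seen. The cause of a change below was not tested unless given. Among genes that passed in both the reported fit and an alternative or leave-one-out fit, 0 had opposite signs. With the opposite sign on the swapped arrays 0 genes passed in both, so that setting says nothing on this. Of 324 gene values named, 302 were past the threshold, and 178 stayed past it under every alternative but the opposite sign and with each array left out.

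Centring each array left each of the 12 counts within 1.5 times the reported one, as did each probe on its own and all probes of the table (1412 in W303-1A with ethanol). With a replicate block in place of the dye term the counts were 1289, 206 and 279 for ethanol in W303-1A, SM1 and CM1, 73, 60 and 41 between strains without ethanol, 906, 631 and 104 with ethanol, and 308, 239 and 16 for the response differences. The filter on missing values tests nothing.

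With quantile normalization the counts were 863 for ethanol in W303-1A and 476 in SM1. Without ethanol they were 303 for SM1 and 261 for CM1 against W303-1A and 153 for CM1 against SM1. With ethanol they were 552, 185 and 40 in the same order, and the response differences from W303-1A gave 220 for SM1 and 144 for CM1. It moved the share of genes higher from 10.2 to 30.7 % for SM1 against W303-1A without ethanol, from 8.7 to 27.6 % for CM1, and from 80.7 to 68.6 % for CM1 against SM1. The trend along the probe number removed gave 163 genes for the CM1 response difference from W303-1A, and moved the share more positive for CM1 minus SM1 from 31.6 to 14.3 %. That share went the other way with array weights, to 60.0 % (45 more positive, 30 more negative), and to 47.6 % without the 2 doubted arrays, so the balance of that contrast is not settled. The other 11 counts were within 1.5 times.

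Without a dye term the counts were 791, 112 and 142 for ethanol in W303-1A, SM1 and CM1, 34, 42 and 31 between strains without ethanol, 511, 292 and 18 with ethanol, and 106, 74 and 5 for the response differences. With array weights they were 799 and 602 for ethanol in SM1 and CM1, 483, 360 and 273 between strains without ethanol, and 870, 518 and 75 for the response differences. The weights moved the share higher from 10.2 to 33.7 % for SM1 and from 8.7 to 28.9 % for CM1 against W303-1A without ethanol, from 80.7 to 60.1 % for CM1 against SM1, and from 71.4 to 61.1 % for the SM1 response difference. With only the groups compared in the fit they were 19 for ethanol in CM1 (residual SD 0.535, 0.613 and 0.463 and weights 0.291, 0.216 and 1.12 on its 3 ethanol arrays), 98 for CM1 against SM1 without ethanol, 574, 40 and 0 between strains with ethanol (603 at an unadjusted p under 0.05 in limma beside the 0), and 114 and 5 for the response differences of CM1 from W303-1A and from SM1. With the normal dye orientation only they were 61 for SM1 against W303-1A without ethanol, 0 for CM1 against SM1 (269 unadjusted in limma), 272 for CM1 against SM1 with ethanol, and 445 and 9 for the response differences of CM1 from W303-1A and from SM1. Without the 2 doubted arrays, SM1 replicate 1 and CM1 replicate 2 with ethanol, they were 158 and 149 for SM1 and CM1 against W303-1A without ethanol and 42 for the response difference of CM1 from SM1. For CM1 against SM1 with ethanol 122 genes passed there, but only 54 of them were among the 138 reported.

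The opposite sign on the swapped arrays gave 0, 1 and 1 genes for ethanol in W303-1A, SM1 and CM1, 0, 0 and 0 between strains without ethanol, 8, 2 and 18 with ethanol, and 0, 1 and 0 for the response differences. Beside the zeros, limma gave 432 genes at an unadjusted p under 0.05 for ethanol in W303-1A, 124, 103 and 32 between strains without ethanol, and 218 and 213 for the response differences of SM1 from W303-1A and of CM1 from SM1. 7 named values changed sign there by construction, since the swapped array then counts against the others: OLI1 -0.052 with ethanol in W303-1A, FET3 0.0055 with ethanol in CM1, SIP18 -0.088 and CTT1 -0.077 for SM1 against W303-1A with ethanol, SDH2 -0.0032 for CM1 against W303-1A with ethanol, CTT1 0.46 for CM1 against SM1 with ethanol, and SIP18 -0.29 for the response difference of SM1. None of the 7 passed there.

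Leaving out 1 array gave 933 to 1226 genes for ethanol in W303-1A, 113 to 209 in SM1 and 141 to 402 in CM1. Without ethanol it gave 32 to 62 for SM1 and 38 to 61 for CM1 against W303-1A, and 7 to 42 for CM1 against SM1. With ethanol it gave 616 to 854, 392 to 1048 and 59 to 181, and for the response differences 151 to 367, 98 to 577 and 1 to 34. The counts moved by over 1.5 times as follows. For ethanol in SM1, without SM1 no-ethanol replicate 1, 2 or 3, 124, 113 and 119 passed. For ethanol in CM1, without CM1 no-ethanol replicate 1, 2 or 3, 166, 169 and 141. For SM1 against W303-1A without ethanol, without W303-1A replicate 1, 2 or 3, 55, 62 and 37, and without SM1 replicate 1, 2 or 3, 53, 32 and 35. For CM1 against W303-1A without ethanol, without CM1 replicate 1 or 3, 45 and 38. For CM1 against SM1 without ethanol, without SM1 replicate 1, 2 or 3, 7, 22 and 21, and without CM1 replicate 1 or 3, 20 and 12. With ethanol, without W303-1A replicate 2 for SM1 against W303-1A, 616. For CM1 against W303-1A, without W303-1A replicate 2 or 3, 418 and 392, and without CM1 replicate 1, 1048. For CM1 against SM1, without SM1 replicate 2 or 3, 59 and 80. For the response difference of SM1 from W303-1A, without W303-1A no-ethanol replicate 2 or 3, 204 and 230, without W303-1A ethanol replicate 3, 223, and without SM1 no-ethanol replicate 2 or 3, 151 and 161. For that of CM1 from W303-1A, without W303-1A no-ethanol replicate 2, 130, without CM1 no-ethanol replicate 2 or 3, 156 and 98, and without CM1 ethanol replicate 1, 577. For that of CM1 from SM1, without SM1 no-ethanol replicate 1, 2 or 3, 6, 1 and 1, without CM1 no-ethanol replicate 1, 2 or 3, 6, 11 and 2, and without CM1 ethanol replicate 1 or 2, 11 and 34.

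Of 160 list calls, 86 were kept with an estimated correlation and 74 lost. Of the same 160, 39 were lost with fry, 25 with quantile normalization, 20 without the 2 doubted arrays, 6 with the trend removed, 3 with the replicate block and 2 with centring. Named gene values fell below the threshold in 57 cases without the dye term, 57 with the normal orientation only, 69 with only the groups compared, 25 with quantile normalization, 11 with the trend removed and 304 with 1 array left out (1977 kept their side of the threshold there). The agreement of ethanol responses was r = 0.526 for W303-1A with SM1 and 0.603 for SM1 with CM1 over genes called in at least 1 of the 2 strains, as the choice of changed genes raises it. Chromosome calls were lost as given earlier. Signal over background was not used here, so its limit on precision is unknown.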

Other observations

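This part reports values from the planned comparisons and no further test of a hypothesis. In all 3 strains 63 genes passed with ethanol, 51 of them higher and 7 lower in each. Besides those named earlier, the shared rises included the phospholipid gene OPI3, the permease gene GIT1, the cell wall genes PIR3 and TIP1, the vacuolar protease gene PEP4 and the peroxiredoxin gene TSA1. The 7 shared falls were CSS1, FCY1, HYP2, MUP1, NRE1, SCS2 and SUT2, named after their values were seen. Passed in 1 strain alone were 1106 genes in W303-1A, 76 in SM1 and 122 in CM1, and such counts do not show a difference between strains, which the response differences test. Among genes called in at least 1 of the strains, r across genes was 0.545 for W303-1A with CM1.

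ANS1 differed among the 3 SM1 arrays with ethanol, at 10.34 on the swapped array and 5.52 and 5.13 on the others. THI6 stood at 5.92, 3.55 and 3.27 on the CM1 arrays with ethanol.

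Of the 695 probes without a gene symbol, 93 passed with ethanol in W303-1A, 21 in SM1 and 35 in CM1. Between strains without ethanol 9, 16 and 6 passed (SM1 and CM1 against W303-1A, then CM1 against SM1), and with ethanol 63, 47 and 11. For the response differences 21, 24 and 2 passed.

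On SM1 replicate 1 with ethanol 859 values lay within 0.01 of 0, against 47 to 241 on the other arrays. The residual SD was highest on CM1 replicate 2 with ethanol, at 0.61. Deviations from the group means correlated between groups at 0.474 to 0.751 for replicates 1, the swapped arrays, 0.195 to 0.491 for replicates 2 and 0.201 to 0.529 for replicates 3. For replicate 2 with replicate 3 of another group they did so at 0.209 to 0.522. The difference of replicates 2 and 3 correlated between groups at -0.170 to 0.0926. Pairing of cultures by replicate number was therefore not seen for replicates 2 and 3, and for replicate 1 it cannot be told from the dye orientation.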
